A study of Mus musculus with 4 samples.

How the data were processed

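RNA was sequenced from 4 libraries of the mouse hippocampal neuronal line HT-22, 2 from wild type cells and 2 from cells overexpressing Nsmce1. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a TruSeq RNA kit and sequencing followed BGISEQ-500 protocols. The submitters' processing notes name HISAT, Cufflinks and the genome build mm9, without versions. How reads were assigned to genes, and whether strand was used, is not given in the sources used here.

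The deposited table holds 1 value per gene and library, as the log2 of a normalised read count plus 1. The normalization by the authors was worked out from the values: after the log2 was undone, all values of a library were whole multiples of 1 step, for 100% of values within a tolerance of 0.001 read. A read was worth 1.26, 1.05, 1.00 and 0.730 normalised reads in wild type replicates 1 and 2 and overexpression replicates 1 and 2. Mitochondrial genes took 5.08% to 5.29% of the reads of a library, and the 10 most abundant genes 5.87% to 6.05%. Of 25050 genes, 0 were at 0 in all libraries. A spreadsheet had turned 26 gene symbols into dates, and 25 were restored from their Ensembl identifiers. Chromosome, gene type, order, overlap, length and GC content came from GENCODE M21 (GRCm38) by identifier, for 15503 of the tested genes. The build differs from the one in the notes, so no coordinates are given. The columns of all 4 samples were matched by their names in the labels.

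The main test was fixed before the data were examined, for either raw counts or FPKM values. The table turned out to hold log2 normalised reads, so the branch for normalised values was used. It fitted limma with a mean-variance trend to the deposited log2 values with group as the only term, over all 4 libraries. The planned minimum in FPKM was replaced by a mean of at least 10 normalised reads, which left 15540 genes and removed 9510. P-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate the change of low genes. With 2 libraries against 2, the smallest exact two-sided permutation p for a single gene is 0.333, so the calls rest on limma's pooled variance, with 4.10 prior and 6.10 total degrees of freedom. For a group without reads, folds are lower bounds against 3 reads over the group's 2 libraries. Intervals of fold changes are 95% limits from limma, and floors cover counting error only.

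The 38 gene lists were written before the data were examined, and the 35 with at least 5 tested genes were compared with all other genes by limma camera with a preset correlation of 0.01. An estimated correlation and fry were set as alternatives at the same time. The plan did not say whether camera should use a variance trend, and both versions had been seen before the default, without it, was kept. With the trend, p53 targets also passed (camera adjusted p = 0.0202). Members were also adjusted over their list alone. That adjustment takes no account of the number of lists, so passing it is weaker than a call over all genes. Named genes were the 4 study genes, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 2 log2 CPM (130 normalised reads), separated groups and a symbol that is not provisional, and the members with the smallest p from each list. These were up to 4 members for a list that passed and for splicing lists, and up to 2 otherwise. Besides the study genes, 11 rises and 13 falls met the rule.

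The steps were tested on simulated data drawn from the real genes' means and depths, 5 runs over 15540 genes with 200 changed genes each. For the comparison of overexpression with wild type, 85.6% of 2-fold and 99.2% of 4-fold changes were recovered, 100% of these with the right sign, beside 11.4 false calls a run. Changed genes had a mean of at least 100 normalised reads, and genes of like abundance shared a replicate spread (dispersion) of at most 0.5. With 200 planted changes the adjusted threshold is easier to reach than with the 30 calls made here. These shares therefore do not give the power for the real genes, and an uncalled gene can still have changed 2-fold. The median SE of a log2 fold change in the real data was 0.133. Each library was counted as a sample. The libraries of a group differed by more than counting noise, with a chi-square per gene of 18.4 in wild type and 25.9 in overexpressing cells, which does not show that they are separate cultures.

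The alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter, a stricter filter of 50 reads in the smallest library (a mean of 62.9 normalised reads), a common median, quantile normalization, equal sums, limma without trend and with robust variances, the replicate number as a block, each library left out, and stricter thresholds. Chosen after seeing the data were limma voom on the recovered reads, thinning to 25787452 reads, camera with a trend, the SMC5/6 list without Nsmce1, the median of each chromosome removed, and the other 2 ways of pairing the 4 libraries. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.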

Results

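Gene expression was measured by RNA sequencing in HT-22, an immortalised line of mouse hippocampal neurons, in 2 groups of 2 libraries: wild type cells and cells overexpressing Nsmce1. The labels also describe the controls as cells in which an inducible Nsmce1 had not been induced. The whole reads behind the deposited values came to 25787452 and 31010351 in the wild type libraries and to 32516117 and 44602989 in the overexpressing libraries. Of 25050 genes in the table, 15540 had a mean of at least 10 normalised reads and were tested. The log2 values of the wild type libraries correlated across genes with r = 0.981 and those of the overexpressing libraries with r = 0.983, against 0.977 to 0.980 between the groups. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

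The comparison asked how the transcriptome of the overexpressing cells differs from that of wild type cells. It also asked whether App, Mapt and Gsap are lower, as the study's description says of Nsmce1 overexpression. The design holds no other contrast. An effect of Nsmce1 therefore cannot be told apart from any other difference between the wild type and the overexpressing cell populations. Nsmce1 (ENSMUSG00000030750, chromosome 7), a RING-type subunit of the SMC5/6 complex that acts in chromosome maintenance and DNA repair, was 14.8-fold higher in the overexpressing cells. Its normalised read count was 1108 and 1206 in the wild type libraries and 17851 and 16525 in the overexpressing ones (log2 fold change 3.89, SE 0.0856, limma adjusted p = 9.06e-05). App (chromosome 16), the amyloid precursor protein, stood at 10954 ± 55.3 normalised reads in wild type and 11469 ± 453 in overexpressing cells (SD, n = 2 in each group). Its log2 fold change was 0.07, with a 95% confidence interval of -0.11 to 0.24 and a limma adjusted p of 0.845. Gsap (chromosome 5), the gamma-secretase activating protein, had a log2 fold change of 0.01, with an interval of -0.29 to 0.30 and an adjusted p of 0.997. Its mean was 598 ± 61.0 normalised reads in wild type and 599 ± 2.74 in overexpressing cells.

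Mapt (chromosome 11), which encodes the microtubule-associated protein tau, was near the lower limit of what these libraries count. It had 21.4 and 15.8 normalised reads in the wild type libraries and 14.0 and 2.92 in the overexpressing ones. The log2 fold change was -1.34, with an interval of -3.15 to 0.48 and a limma adjusted p of 0.718. Adjusted over the 4 study genes alone, limma gave Mapt an adjusted p = 0.244, App an adjusted p = 0.520 and Gsap an adjusted p = 0.963. The depth does not separate an unchanged Mapt from one several-fold lower, and its log2 fold change was -0.37 without overexpression replicate 2 and -2.31 without overexpression replicate 1 (limma adjusted p = 0.897 and 0.494). The genes of chromosome 16 had a median log2 fold change of 0.18, and with the median of each chromosome removed App stood at -0.097, with an interval of -0.27 to 0.080. A single median was removed, while parts of chromosome 16 had medians from 0.08 to 0.29. The removal can therefore take too much or too little from App, and its sign is not settled. The same limit holds for the other chromosome 16 genes given below.

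**Figure D1:**
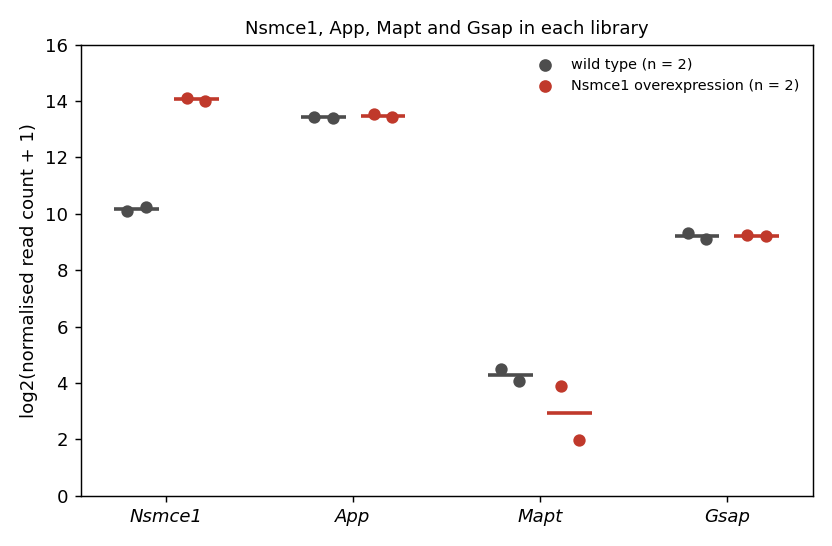
Each point is a library and each horizontal line the mean of its group of 2, on a vertical axis of log2(normalised read count + 1). Nsmce1 is 3.89 log2 units higher in the overexpressing cells, App and Gsap lie within 0.07 of the wild type mean, and Mapt is at 21.4 and 15.8 normalised reads in wild type and 14.0 and 2.92 in the overexpressing cells.

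In all, 16 genes were higher and 14 lower with Nsmce1 overexpression (limma, Benjamini-Hochberg adjusted p under 0.05), and 22 of the 30 changed at least 2-fold. Crk, an adaptor protein of tyrosine kinase signalling, rose 3.59-fold from 2040 ± 68.7 to 7330 ± 261 normalised reads (log2 fold change 1.84, SE 0.0779, adjusted p = 0.00119). Pcyt1a, the rate-limiting enzyme of phosphatidylcholine synthesis by the CDP-choline route, rose 2.79-fold, and Ipmk, an inositol polyphosphate kinase, 2.78-fold. Ms4a4d, a membrane-spanning protein, rose 3.57-fold, Slc36a1, a proton-coupled amino acid transporter, 2.67-fold, and Tnfaip1, an adaptor of a cullin ubiquitin ligase, 2.49-fold. Smaller rises were in Kdm2a, a histone lysine demethylase (4309 to 8610 normalised reads), Piga, an enzyme of GPI anchor synthesis (1.82-fold), the tyrosine kinase Src (1.77-fold) and Anp32e, a chaperone of the histone variant H2A.Z (1.71-fold). Ipmk lies on chromosome 10, whose genes had a median log2 fold change of 0.14, and with the median of each chromosome removed it went from 1.47 (SE 0.158) to 1.33 (SE 0.154) and missed the threshold (limma adjusted p = 0.0538). The log2 fold changes of these 10 genes had standard errors between 0.0779 and 0.190.

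The largest fall was in Aox3, an aldehyde oxidase, which had 3952 and 3383 normalised reads in the wild type libraries and 8 and 3.65 in the overexpressing ones (log2 fold change -9.14, SE 0.326, adjusted p = 0.000851). Aox1, its neighbour in the same gene family, had 868 and 758 in wild type and 818 and 631 in overexpressing cells. Slc7a11, the cystine and glutamate exchanger that supplies cysteine for glutathione, fell by 3.58 on the log2 scale, from 615 ± 64.1 to 50.8 ± 9.66 normalised reads. The cytochrome P450 gene Cyp3a41a was 7.19-fold lower at low levels, and its reads can be split with a near-identical copy, which leaves its value uncertain. Plcb4, a phospholipase C of receptor signalling, was 4.17-fold lower, Slc35a4, a member of the nucleotide sugar transporter family, 3.78-fold, and the zinc transporter Slc39a9 3.18-fold. Krcc1 was 3.07-fold lower, the phosphatase gene Ctdsp2 2.97-fold, Spcs2, a subunit of the signal peptidase, 2.58-fold, and Fam57a 2.41-fold.

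The other genes past the threshold fell outside the rule for named genes, and are named here after their values were seen. Atp2b1, a plasma membrane calcium pump on chromosome 10, was 1.66-fold higher, and with chromosome medians removed its log2 fold change went from 0.73 (SE 0.0764) to 0.59 (SE 0.0765, limma adjusted p = 0.0640). Gm21887, Gm45062 and Ramp2 had 0 reads in both wild type libraries and were at least 327-fold, 172-fold and 52.8-fold higher, where the floor was 3 reads over the 2 libraries of the group. Gsdmd, the pore-forming effector of pyroptosis, had 0 and 2.11 normalised reads in wild type and 151 and 99.3 in overexpressing cells. Dyrk4, a protein kinase, was 9.08-fold lower, Trim26 1.98-fold, Pacsin2 1.73-fold and Oxct1, an enzyme of ketone body use, 1.54-fold. In the reference annotation 9 of the 30 genes overlap another tested gene. The reads of Gm45062, Ramp2, Krcc1, Anp32e and Pacsin2 can be shared with a gene on the same strand. Slc39a9, Spcs2, Fam57a and Oxct1 overlap a gene on the opposite strand, whose reads can be shared if strand was not used, which is not given. Glcci1, which overlaps Gm45062, went from 854 and 668 to 209 and 280 normalised reads.

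An unadjusted limma p under 0.05 was reached by 1230 genes, where 777 are expected by chance. The 777 rests on limma's pooled variance and is not a firm baseline here. The other 2 ways of pairing the libraries gave 762 and 295 such genes. In those pairings a group difference adds to the spread within each pair and lowers the count. They therefore give no baseline for the 1230 either. Part of the excess lies on chromosomes 10 and 16, whose genes were shifted upwards as a whole. Among genes of at least 100 normalised reads, chromosome 10 had 123 of them higher and 5 lower, and chromosome 16 had 106 and 10. Among genes of at least 1000 normalised reads, the groups parted 8 by at least 2-fold with close replicates, Nsmce1, Crk, Pcyt1a, Tnfaip1, Slc39a9, Krcc1, Spcs2 and Ctdsp2, while each of the other 2 ways of pairing the libraries parted 4. The number of calls varied with the library left out: it fell without either wild type library and rose without either overexpressing library. In such a fit a group holds a single library, and the spread comes from the pair of the other group. All 30 called genes kept their sign in each of these fits.

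**Figure D2:**
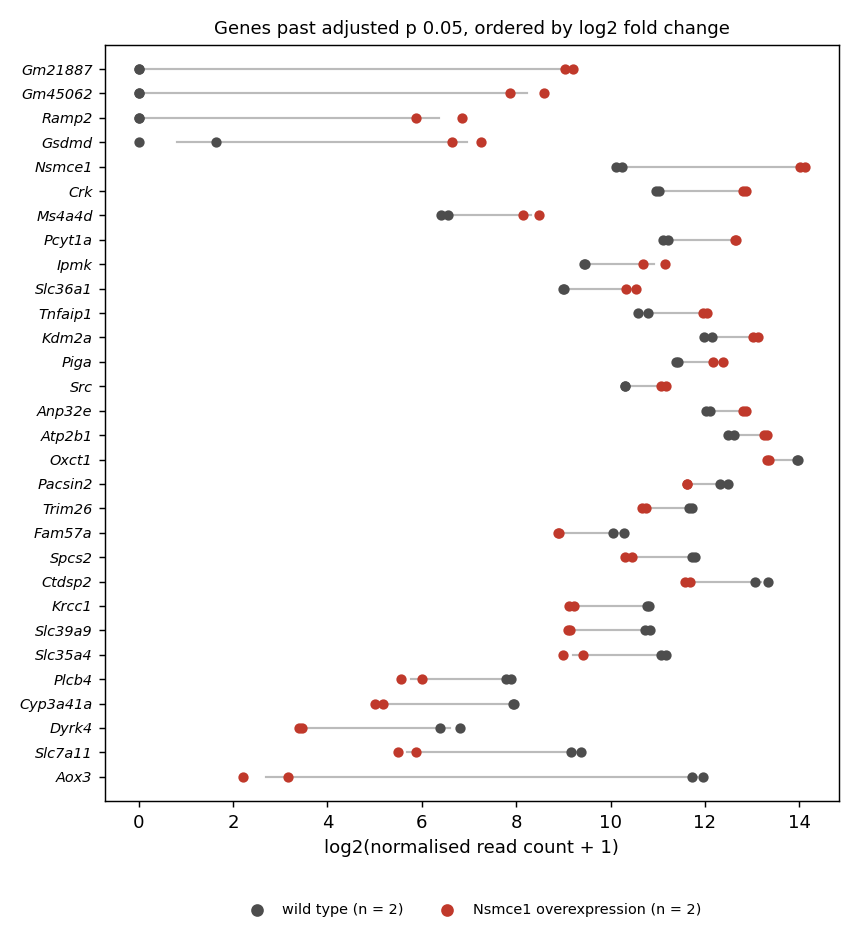
Each row is one of the 30 genes past an adjusted p of 0.05, with a point per library on an axis of log2(normalised read count + 1) and a line between the group means. The 16 genes at the top are higher and the 14 at the bottom lower with Nsmce1 overexpression, from Gm21887, at 0 in both wild type libraries, to Aox3 with a log2 fold change of -9.14.

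The study's title concerns alternative splicing. The table holds 1 value per gene, so transcript isoforms were not analysed here, and the genes that carry out or steer splicing were compared instead. None of the 4 lists of splicing genes passed its set test (limma camera) and 0 of their members were called over all genes tested. Of 34 core spliceosome genes, 14 lay above and 20 below 0 (median log2 fold change -0.02, adjusted p = 0.981, with the test itself leaning up). Snrnp70, a U1-specific spliceosome protein, was the only one past the threshold adjusted over the list alone. It had 5267 ± 174 normalised reads in wild type and 8243 ± 633 in overexpressing cells (log2 fold change 0.64, SE 0.0845, limma adjusted p = 0.0731 over all genes). Snrpf, Snrpd3 and Sf3a2, all on chromosome 10, had log2 fold changes of 0.24, 0.18 and 0.18, and of 0.092, 0.038 and 0.031 with chromosome medians removed. Among 14 SR proteins, 5 lay above and 9 below 0 (median -0.03, adjusted p = 0.952). Tra2b, on chromosome 16, stood at 0.10 (-0.065 with chromosome medians removed), Srrm1 at -0.09, Srsf1 at 0.07 and Srsf4 at -0.06, and 0 of the list passed the adjustment over the list alone.

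The 26 hnRNP genes, which encode RNA-binding proteins of pre-mRNA, divided into 13 above and 13 below 0 (adjusted p = 0.981). Hnrnph3, on chromosome 10, had a log2 fold change of 0.30 (0.16 with chromosome medians removed), Ptbp3 0.17, Syncrip -0.24 and Hnrnpul2 0.16. Of 16 tested tissue-specific splicing regulators, 11 lay above and 5 below 0 (median 0.06, adjusted p = 0.726). The neuronal regulators Celf5, on chromosome 10, and Nova1 stood at 0.33 (0.19 with chromosome medians removed) and -0.32, Elavl3 at -1.54 from low counts, and Celf2 at 0.16.

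The SMC5/6 complex, in which Nsmce1 works, had 9 tested members, with Nsmce1 as the 1 called gene, and did not pass its set test (median 0.07, adjusted p = 0.174). Without Nsmce1, 6 of the other 8 lay above 0, with a median of 0.05, and Slf1 stood at 0.17. Cohesin and condensin genes, the related chromosome-holding complexes, had 13 of 17 above 0 (median 0.06, adjusted p = 0.676), with Ncapd3 at 0.14 and Smc3 at -0.12. Homologous recombination and Fanconi genes divided into 13 and 13, with a median of 0.002 and an adjusted p of 0.981. The helicase gene Blm stood at 0.23 and Rad50 at -0.19. Replication genes had 19 of 34 above 0 (median 0.02, adjusted p = 0.676), with Ccne1 at 0.30 and Mcm4, on chromosome 16, at 0.20 (0.038 with chromosome medians removed). Mitosis genes had 13 of 28 above 0 (median -0.01, adjusted p = 0.981), with Cenpf at 0.17 and Aurkb at -0.14. Of 23 p53 targets, 21 lay above 0, with a median of 0.11, an adjusted p of 0.127 and 0 called members. Trp53inp1 stood at 0.31 and the cell cycle inhibitor Cdkn1a at 0.32. The RING ubiquitin ligases near MAGE and p53 had 5 of 11 above 0 (median -0.01, adjusted p = 0.981), with Rnf168, on chromosome 16, at 0.26 and Mdm2, on chromosome 10, at 0.27 (0.095 and 0.13 with chromosome medians removed).

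For amyloid precursor processing, 14 of 24 tested genes lay above 0 (median 0.03, adjusted p = 0.981, with the test itself leaning down), and 1 passed adjusted over the list alone. That gene was Mme, encoding neprilysin, a peptidase that degrades amyloid beta. It had 46.5 and 37.9 normalised reads in the wild type libraries and 0 in both overexpressing ones, at least 33.1-fold lower, with a limma adjusted p of 0.0584 over all genes. It passed over all genes in some of the other settings, among them limma without a trend (adjusted p = 0.0228) and with voom (adjusted p = 0.0349). Clu, encoding clusterin, had 22.6 and 0 normalised reads in wild type and 93.0 and 85.4 in overexpressing cells (limma adjusted p = 0.520). Tau kinases and phosphatases had 15 of 23 above 0 (median 0.06, adjusted p = 0.676). The tau kinase Gsk3b, on chromosome 16, had 4868 ± 179 normalised reads in wild type and 6506 ± 160 in overexpressing cells. Its log2 fold change of 0.42 passed adjusted over the list alone but not over all genes (limma adjusted p = 0.168). With chromosome medians removed it was 0.26 (SE 0.0770, limma adjusted p = 0.543 over all genes), and the adjustment over the list alone was not repeated.

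Of the 35 lists with at least 5 tested genes, 2 passed camera with its preset correlation, both lower in the overexpressing cells. Ribosomal protein genes lay below 0 in 31 of 32 cases, with a median log2 fold change of -0.14 (adjusted p = 0.000187, and adjusted p = 0.981 with an estimated correlation). Rpl11, Rps20 and Rps6 had log2 fold changes of -0.30, -0.41 and -0.16. Cholesterol biosynthesis genes lay below 0 in 21 of 23 cases, with a median of -0.24 (adjusted p = 0.000346, and adjusted p = 0.981 with an estimated correlation). The sterol enzymes Nsdhl and Ebp had log2 fold changes of -0.37 and -0.26. No single member of either list was called over all genes or adjusted over the list alone. The sterol list rested on overexpression replicate 2: without it the median was -0.08 (adjusted p = 0.484), and without overexpression replicate 1 it was -0.33. Without wild type replicate 2 neither list passed: the median of ribosomal proteins was -0.067 (adjusted p = 0.175) and that of cholesterol biosynthesis -0.21 (adjusted p = 0.0624). Ribosomal proteins also missed the threshold without overexpression replicate 2 (median -0.11, adjusted p = 0.0646).

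**Figure D3:**
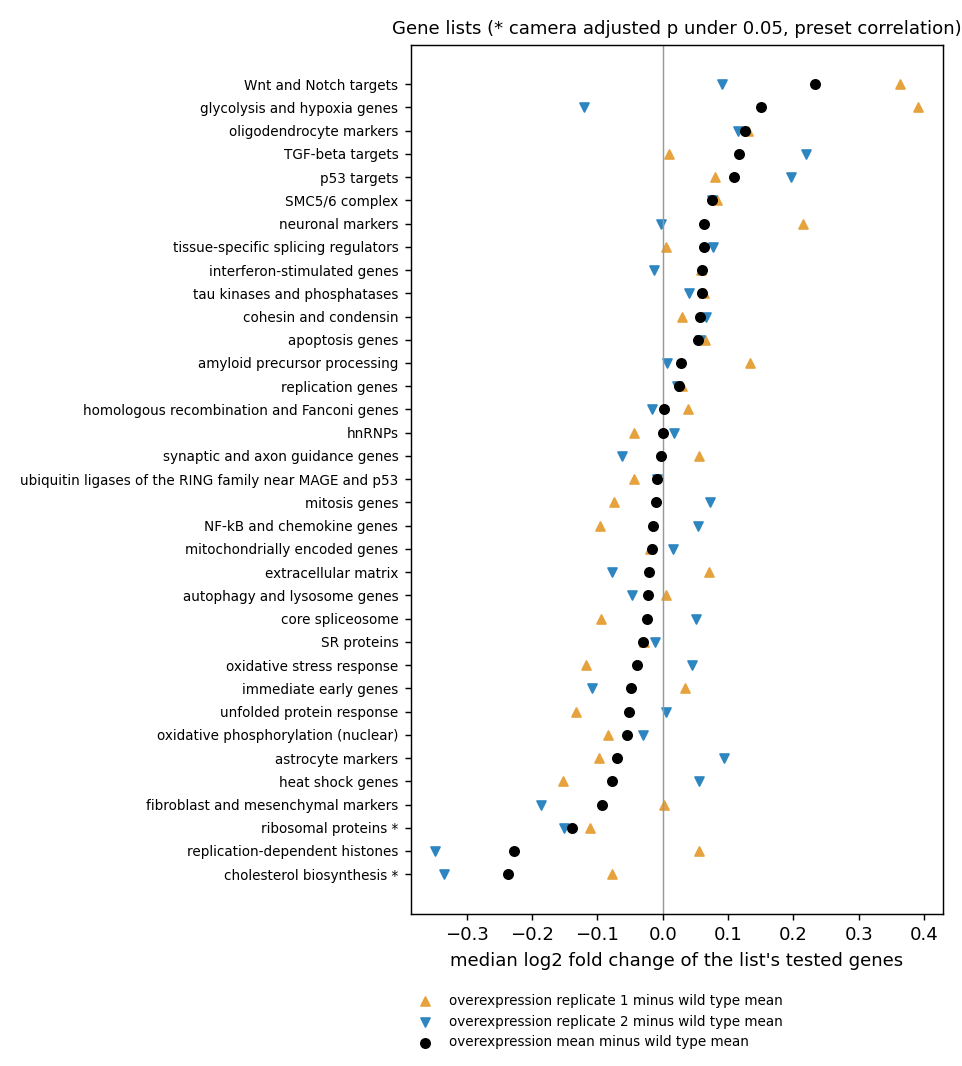
Each row is a gene list, and the horizontal axis is the median log2 fold change of its tested genes: black for both overexpressing libraries, triangles for each overexpressing library against the wild type mean. Ribosomal proteins (-0.14) and cholesterol biosynthesis (-0.24) carry a star for an adjusted p under 0.05, and the 2 overexpressing libraries stand on opposite sides of 0 for 19 of the 35 lists with a set test, among them glycolysis and hypoxia genes (0.39 and -0.12).

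The remaining lists did not pass, and in 19 of the 35 lists tested the 2 libraries lay on opposite sides of 0 against the wild type mean. HT-22 cells expressed few markers of mature neurons: 8 of 25 were tested, with a median of 0.06 (adjusted p = 0.981). The growth cone gene Gap43 had 23.9 and 44.2 normalised reads in wild type and 7 and 0 in overexpressing cells (limma adjusted p = 0.460), and Syn2 stood at 1.84 from low counts. Synaptic and axon guidance genes had 8 of 17 above 0 (median -0.002, camera adjusted p = 0.726), with Sema3a at -0.63 and L1cam at -1.28 from low counts. Among markers of other cell types, astrocyte markers had 2 of 5 above 0 (median -0.07, adjusted p = 0.726). Aldh1l1 at -2.14 and the glutamate transporter Slc1a3 at 0.49 passed adjusted over the list alone, in opposite directions. Oligodendrocyte markers had 4 of 5 above 0 (median 0.13, adjusted p = 0.726), with Cspg4 at -0.11. Fibroblast and mesenchymal markers had 5 of 17 above 0 (median -0.09, adjusted p = 0.485), with Postn at -0.79 and Col3a1, at 75211 and 58451 mean normalised reads, at -0.37. Microglia and leukocyte markers and endothelial markers had 3 tested genes each, too few for a set test. Tmem119, a microglial membrane protein, stood at -0.38 and passed adjusted over the list alone but not over all genes (limma adjusted p = 0.465). Cd68 stood at 0.54, and Flt1 and Vwf at 0.27 and 0.13 from low counts.

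Stress and signalling lists gave the same outcome. The oxidative stress response, with Slc7a11 as its 1 called gene, had 10 of 21 above 0 (median -0.04, adjusted p = 0.726), and Prdx1, a peroxiredoxin at 0.43, passed adjusted over the list alone. The unfolded protein response had 7 of 21 above 0 (median -0.05, adjusted p = 0.490), with Canx at -0.26 and Asns at -0.41. Heat shock genes had 5 of 12 (median -0.08, adjusted p = 0.726), with Hsp90ab1 at -0.19 and Dnaja1 at -0.16. Immediate early genes had 8 of 22 (median -0.05, adjusted p = 0.697), with Egr1 at -0.53 and Fosl2 at 0.37. Interferon-stimulated genes had 13 of 24 (median 0.06, adjusted p = 0.676), with Oas1a at 1.40 and Mx1 at 0.74 (chromosome 16, 0.58 with chromosome medians removed). NF-kB and chemokine genes had 7 of 16 (median -0.01, adjusted p = 0.981), with Nfkbia at 0.33 and Nfkb2 at -0.19. Apoptosis genes had 12 of 21 (median 0.05, adjusted p = 0.676), with Endog at 0.90 and Birc2 at 0.30. Autophagy and lysosome genes had 10 of 25 (median -0.02, adjusted p = 0.726), with Map1lc3b at -0.45 and Sqstm1 at -0.29.

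Extracellular matrix genes had 11 of 25 above 0 (median -0.02, adjusted p = 0.952, with the test itself leaning up). Col8a1 at 0.51 (chromosome 16, 0.35 with chromosome medians removed), Mmp9 at 1.03 and Timp3 at 0.42 passed adjusted over the list alone. TGF-beta targets had 9 of 14 (median 0.12, adjusted p = 0.726), with Ctgf at -0.58 (chromosome 10, -0.73 with chromosome medians removed), which passed over the list alone, and Skil at 0.59. Wnt and Notch targets had 4 of 6 (median 0.23, camera adjusted p = 0.981). Jag1 at -0.70, Ccnd1 at -0.34 and Hey1 at 0.76 passed over the list alone. They did not pass over all genes (limma adjusted p = 0.267, 0.303 and 0.418). Glycolysis and hypoxia genes had 18 of 23 (median 0.15, camera adjusted p = 0.676). Aldoc stood at -1.14 from low counts and Hk1 at 0.50 (chromosome 10, 0.35 with chromosome medians removed). Nuclear genes of oxidative phosphorylation had 11 of 30 (median -0.06, adjusted p = 0.481), with Cox5b at -0.29 and Ndufb8 at -0.25. Mitochondrially encoded genes had 3 of 13 (median -0.02, camera adjusted p = 0.981), with mt-Co3 at -0.07. In this list mt-Atp6 had 25721 and 81431 normalised reads in wild type and 108540 and 109290 in overexpressing cells. By contrast mt-Atp8 had 36451 and 36568 in wild type and 35434 and 35747 in overexpressing cells. The wild type libraries thus differed from each other in mt-Atp6 but hardly in mt-Atp8. Whether reads of mt-Atp6 were counted differently between libraries was not tested. Replication-dependent histones had 3 of 12 (median -0.23, with 0.06 and -0.35 in the 2 overexpressing libraries, adjusted p = 0.382), with Hist1h2ab at -0.86 and Hist1h1b at 1.11, both from low counts.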

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

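Voom on the recovered reads, thinning and removal of chromosome medians were chosen after seeing the data. In every setting run the 30 called genes with a value kept their sign. The counts of calls moved more. Genes higher, 16 as reported, were 10 with a pseudocount of 0.1, 7 with no filter (more genes tested), 8 with quantile normalization, 5 without a variance trend, 32 with robust variances, 9 with voom and 5 at an adjusted p of 0.01. Genes lower, 14 as reported, were 9 with no filter, 4 without a trend, 40 with robust variances and 6 at an adjusted p of 0.01. Leaving out each library gave 2 to 33 genes higher and 0 to 42 lower, with the lone library of a group assumed to vary like the others: the lowest counts, 2 and 0, came without wild type replicate 1, and the highest, 33 and 42, without overexpression replicate 2. Of the 30 genes, 2 were still called without wild type replicate 1, 5 without wild type replicate 2, 20 without overexpression replicate 1, 21 without overexpression replicate 2, 4 without a trend, 18 with quantile normalization, 18 with voom, 21 after thinning and 27 with chromosome medians removed, which ended the calls of Ipmk, Atp2b1 and Plcb4 (-2.06 to -2.04, adjusted p = 0.0538). Beyond fewer samples or more genes tested, the cause was not tested.

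With the replicate block, 24 genes were higher and 36 lower and the lists stayed at 2. The samples share only a number: the deviations of the libraries numbered 1 from their group means had a correlation of 0.0068 across genes. Snrnp70 was called with the block (adjusted p = 0.0480).

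Nsmce1 kept its call everywhere, from 3.83 to 3.95 with libraries left out. App, Mapt and Gsap were called in no setting. App ranged from 0.03 to 0.11 with libraries left out and was -0.097 with chromosome medians removed. Gsap ranged from -0.10 to 0.11 and was below 0 only without wild type replicate 2. Mapt ranged from -2.31 to -0.37 and has no value under the stricter filter. Of genes named as values, Tra2b was -0.065 with chromosome medians removed. With libraries left out, Syn2 ranged from -0.22 to 3.90, Celf2 from -0.00205 to 0.31, Flt1 from -0.21 to 0.74 and Vwf from -0.61 to 0.87, with -0.45 without overexpression replicate 1. Named genes not called as reported but called elsewhere were Mme (adjusted p = 0.0494 with a pseudocount of 5, 0.0228 without a trend, 0.0242 with robust variances, 0.0349 with voom and 0.0444 without overexpression replicate 2), Snrnp70 (0.0279) and Ctgf (0.0464) with robust variances, mt-Atp6 without wild type replicate 2 (0.0311) and Hk1 without overexpression replicate 2 (0.0329).

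The lists called, 2 as reported, ranged from 0 to 6 with libraries left out: 0 without wild type replicate 2, 6 without overexpression replicate 1 and 1, glycolysis and hypoxia genes, without overexpression replicate 2. They were 0 with an estimated correlation and 0 with fry for a shift in one direction, and 3 with voom and with camera's trend, which added p53 targets. The mixed test of fry, which counts changes in both directions together, passed for some lists. Lowest were amyloid precursor processing and the SMC5/6 complex, which includes Nsmce1 (fry mixed adjusted p = 0.00728 for each). Astrocyte markers, the oxidative stress response, extracellular matrix and replication-dependent histones also passed (fry mixed adjusted p = 0.0180 for each). Wnt and Notch targets passed as well (fry mixed adjusted p = 0.0334). How far members at low counts, such as Mme and Clu in the amyloid list, carried these results was not tested. The median of glycolysis and hypoxia genes was -0.12 without overexpression replicate 1 and 0.39 without overexpression replicate 2.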

Other observations

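The neighbour test, the tests of zero counts by other pairings and by overlap, and those of depth and of length and GC for the called genes were set before their results were seen; the tests of chromosomes 10 and 16, of 2-fold steps in abundant genes and of zeros by read sampling were chosen after.

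The 2 overexpressing libraries differed from each other in genes of the hypoxia response and glycolysis. Hk1, a hexokinase, had 12620 normalised reads in overexpression replicate 1 and 7760 in replicate 2, beside 6789 and 7202 in wild type. Bnip3, a hypoxia-induced mitophagy receptor, had 10916 and 5408, beside 6178 and 6447. P4ha1, a collagen prolyl hydroxylase, had 14501 and 9332, Ndrg1 12024 and 6422, and Pdk1, a kinase that inhibits pyruvate dehydrogenase, 7462 and 4227. Against the wild type mean the list's median was 0.39 in replicate 1 and -0.12 in replicate 2. Sterol genes were also lower in replicate 2 than in replicate 1: Cyp51 had 10611 and 7904 normalised reads, beside 11090 and 11605 in wild type.

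The genes of chromosomes 10 and 16 were shifted upwards: among genes of at least 100 normalised reads, the 571 of chromosome 10 had a median log2 fold change of 0.14 and the 350 of chromosome 16 one of 0.18, against -0.03 to 0.04 in the other 18 chromosomes, and 80.7% and 80.9% of these genes lay above 0, against 49.3% elsewhere. Both overexpressing libraries showed it (0.14 and 0.15 for chromosome 10, 0.17 and 0.19 for chromosome 16), and the other 2 pairings of the libraries gave 0.01 and -0.002 and 0.02 and -0.01. After length and GC trends were removed the median of chromosome 10 kept 0.901 of its value and that of chromosome 16 was 0.16, which argues against those trends as the whole cause, and the adjacent-gene correlation of -0.000968, below the 0.0042 to 0.038 of shuffles within chromosomes, leaves smaller shared segments undecided. A hypothesis is a higher copy number of both chromosomes in part or all of the overexpressing cells. With each chromosome cut into 4 parts of equal gene number, the lowest of these 8 parts had a median of 0.078 and the highest of the 72 others 0.069. Both chromosomes were picked for their high medians over these same genes. The parts are therefore no separate support for the hypothesis, and show only that the shift was spread along each chromosome. The parts of chromosome 16 ranged from 0.08 to 0.29, and the first part of chromosome 11 (-0.14) and the last of chromosome 19 (-0.16) were lower by as much, so whole-chromosome gain alone does not cover the pattern and other regional causes stay open.

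The median absolute log2 fold change of the called genes was 1.01 times its value after thinning to equal depth. Thinning leaves the expected ratio between normalised libraries as it was, so this value cannot decide on depth as a cause. After removal of length and GC trends the median was 1.004 times its value. These trends had an SD of 0.038 across genes, against a median of 1.59 for the called genes. That argues against length and GC trends as the whole cause of these fold changes. After thinning 9 of the 30 lost their call, at limma adjusted p of 0.0514 to 0.0614. The median absolute log2 fold change of these 9 was 0.87 before and 0.86 after. The median SE over all 30 was 0.104 before and 0.106 after. Single libraries also stood at least 2-fold apart in 29 abundant genes whose other 3 libraries lay close together. Rlf had 1184 normalised reads in overexpression replicate 1 and 5701, 5666 and 5871 elsewhere, and Grb2 1619 in wild type replicate 2 and 3246, 3268 and 3616 elsewhere. Such steps may come from reads of a gene counted differently between libraries; the groups parted 8 abundant genes in this way and the other pairings 4 and 4, which does not decide whether Crk, Pcyt1a, Tnfaip1, Slc39a9, Krcc1, Spcs2 and Ctdsp2 are of this kind. The other 2 pairings called 9 and 5 genes in all, against 30, and 3 pairings are too few for a share under 0.05. A group difference also adds to the spread within those pairs and lowers their counts.

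Genes with 0 reads in both libraries of a group and at least 20 normalised reads in both of the other numbered 7: Mme, off in overexpressing cells, and Gm21887, Gm45062, Ramp2, Gm21994, Stard8 and Ugt1a9, off in wild type. Read sampling alone cannot give such zeros, but this follows from the rule that picked the genes. With at least 20 normalised reads in both libraries of the other group, the chance is small for any gene that enters. The largest binomial chance of such zeros under equal expression, times the genes tested, was 2.63e-13. The other pairings gave 6 and 3, so genes switched between libraries whatever their group cannot be told apart from an effect of the group with 7 genes. Of the 7, 42.9% overlap another tested gene, equal to the median of 10000 expression-matched draws: the bound set beforehand counts this against shared reads, but it was tightened to the lower limit of the draws (14.3%) after the value was seen, because 7 genes are few, and shared reads are left open. Some members of the protocadherin gamma cluster, picked after their values were seen, differed between libraries irrespective of group. Pcdhga2 had 4142 and 7.37 normalised reads in the wild type libraries and 11 and 3058 in the overexpressing ones. Pcdhgb5 had 11.3 and 3514 in wild type and 5 and 26.3 in overexpressing cells, and Pcdhgb2 91.8 and 47.4, and 2964 and 76.6. Each library thus had a different high member or repeated one. Whether the genes were switched, or their reads counted under different members, was not tested.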
